A study of Arabidopsis thaliana with 3 samples.

How the data were processed

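SPL10 binding was measured by DAP-seq in leaf material of Arabidopsis thaliana Col-0, in 2 precipitated samples and 1 input. Per the labels' protocols, cells were fixed with formaldehyde and the chromatin sheared by sonication, although DAP-seq as usually described uses purified genomic DNA and a protein made in vitro. How the protein was made is not given in the sources used here. The submitters' processing notes name cutadapt, without a version, and the TAIR10 genome build. The input file was an alignment log of read-pair counts and percentages as deposited, in which 2 lines reported a file that could not be opened. Reads themselves were not used here.

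Each precipitated sample had its own peak list, so peaks were called per replicate and not on pooled samples. Peak names in the lists name MACS as the caller, while its version, threshold and control library are not given in the sources used here. The deposited fold enrichment at the summit is a ratio to the caller's background. The lists as deposited also give −log10 p and −log10 q at the summit, and the deposited score was within 1 of 10 times the −log10 q for every peak. Widths ran from 198 bp, with medians of 311 and 310 bp. A share of 10.8% of the replicate 1 peaks and 7.99% of the replicate 2 peaks had a q above 0.05, so the lists were not limited by that threshold. Mitochondrial peaks (74 and 76) were kept apart and no plastid peaks were listed.

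Tag numbers were recovered from the deposited fold and −log10 p, since both follow from the whole number of tags at the summit, a scaling factor and the background. Recovery on simulated lists with known tag numbers returned 100% of 6000 summits. In the deposited lists 100% of p-values were matched in each replicate. The scaling put replicate 1 at 1.26 times and replicate 2 at 1.18 times the depth of the background library, and the genome-wide background was 10.2 tags for both lists. The highest tag number was 396 in both, which is 2 times the narrowest peak width of 198 bp. Counting intervals for fold are exact Poisson intervals of the recovered tags at the given background, at the 95% level. They take no account of the highest tag number and were left out for named summits with over 198 tags.

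Peaks of the 5 nuclear chromosomes were called shared at a reciprocal overlap of at least 50%, with the summit at the mean of both summits. Agreement was tested by 1000 random placements within chromosomes. The comparison of tag numbers between replicates used an exact binomial test per shared peak. Because the replicates split their tags at shared peaks more evenly than binomial sampling gives, they were counted as 1 sample. Independent libraries with a tag ceiling can do so too, and peaks called in only 1 replicate were left out. The tags were those at each replicate's own summit and not in a common window, so independent libraries need not reach the binomial value. Counting them as 1 sample is therefore a cautious choice and not evidence of a shared library. Nothing in the labels says that they came from separate plants, so tests over peaks measure placement and counting only.

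Genes and symbols came from a RefSeq table of the TAIR10.1 assembly, whose gene coordinates are not printed and were used for neighbours and distances. Of 38312 table rows, 37899 nuclear genes were kept, and all 182 genes of the 13 fixed lists were found by locus tag. The table has no strand and no reference sequence was used, so 2 planned parts changed. Promoters were replaced by flanks on both sides, from 2000 bp outside either annotated end to 200 bp inside it, and the window at REV was 5000 bp on each side. The search for the GTAC core recognised by SBP domains, and the list background matched on it, were not run. UTRs, exons and introns were not told apart.

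A gene was called bound when a shared summit lay in its flanks. Each list was compared with other nuclear genes, or with genes of the same kinds where it held microRNA genes, by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 13 lists and a threshold of 0.05. The fold of a list's bound members was placed among 10000 random lists of bound genes, without matching on gene-free bases or adjustment over the 13 lists. Locations and density in 100 kb bins were tested by 1000 random placements, two-sided. Placements drew on every position of a chromosome, with no allowance for DNA where reads cannot be placed. On simulated data, 50% planted sharing was returned as 50%, and 2.9% of 1000 random lists of 19 genes had p under 0.05. Of 1000 simulated lists whose members were each bound with a chance of 80%, 45.9% passed 0.05 divided by 13 with 19 members and 25.9% with 12, against 6% and 4% at a chance of 65%, so lists of this size can miss such a difference.

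Named genes were REV and the other HD-ZIP III genes, at most 4 bound members per list with the highest mean log2 fold, and the 10 strongest shared peaks. A peak named by a gene could lie nearer to, or inside, another gene. The naming rule, the lists and the other settings were fixed before the data were examined. These settings were other overlap rules, −log10 q of at least 10, the 5000 peaks of highest fold, each replicate alone, flanks of 1000 bp, flanks with gene bodies, and placement within 100 kb. Settings chosen after seeing the data were q of at most 0.05, flanks counted before gene bodies, other list backgrounds, summits rotated along chromosomes, the recovered tag numbers and a screen of genes grouped by symbol. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.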

Results

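DNA sites bound by SPL10 were mapped in leaf material of the Arabidopsis thaliana ecotype Col-0 by DAP-seq. SPL10 is an SBP-domain transcription factor, of a family that is targeted in part by the microRNA miR156. DNA affinity purification sequencing recovers the genomic DNA that a transcription factor retains and compares it with an input library. The series held 3 samples: 2 SPL10 precipitations, each with its own list of called peaks, and 1 input, of which an alignment log was read. The input log counted 19553456 read pairs, of which 60.02% aligned concordantly at a single place and 17.55% at more than 1, for an overall alignment rate of 82.31%. The lists held 21574 peaks (replicate 1) and 21439 peaks (replicate 2), and the median summit carried 47 and 45 recovered tags. Fold enrichments, −log10 q and positions were the authors' own values per peak. Counting intervals (95%, exact Poisson on the recovered tags) cover counting error only, and are not given for summits with over 198 tags, where the highest tag number found, 396, limits the count. Over their shared peaks, with tags taken at each replicate's own summit, the replicates differed by less than binomial sampling gives. They were counted as 1 sample, so both values are given and no standard deviation is.

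The series title names REVOLUTA (REV, AT5G60690), an HD-ZIP III gene that promotes adaxial, or upper-side, leaf identity, as the gene whose transcription SPL10 promotes. Inside REV, a shared peak lay on chromosome 5 at 24400803 to 24401009 in replicate 1 (TAIR10). Its fold enrichment was 2.79 (counting interval 2.03 to 3.74, 42 tags) in replicate 1 and 3.44 (2.55 to 4.53, 48 tags) in replicate 2. A second shared peak stood 4100 bp past the higher-coordinate end of the gene in replicate 1, at 2.64-fold (1.87 to 3.62) and 2.50-fold (1.74 to 3.50). Replicate 1 alone had a peak 2374 bp off the lower-coordinate end at 2.57-fold (1.81 to 3.53), and replicate 2 alone had a peak 1507 bp off the higher-coordinate end at 2.35-fold (1.62 to 3.32). No shared peak stood in the 2000 bp flanks of REV.

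Compared with the rest of the genome, the REV peaks were weak. The stronger one, at a mean of 3.10-fold, ranked at percentile 36.5 of all shared peaks, whose median was 3.75-fold. Among protein-coding genes, 52.2% had at least as many shared peaks within 5000 bp. Neither peak was left when only peaks with −log10 q of at least 10, or only the 5000 peaks of highest fold, were kept. REV was chosen by the study, so its peaks are not independent evidence, and which end of the gene is the promoter was not used here.

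Of the 5 HD-ZIP III genes, 3 had a shared peak in their flanks. ATHB-8 (AT4G32880), which acts in vascular development, had the strongest, at 13.1-fold (11.3 to 15.1) and 13.4-fold (11.5 to 15.6), on chromosome 4 at 15869353 to 15869876, outside genes and 959 bp past the higher-coordinate end. PHB (AT2G34710), a polarity gene closely related to PHV, had a peak of 4.90-fold (3.83 to 6.19) and 6.12-fold (4.87 to 7.60), and ATHB-15 (AT1G52150) one of 5.32-fold (4.2 to 6.66) and 5.29-fold (4.14 to 6.68). The ATHB-15 summit lay 1544 bp off, inside another coding gene. A stronger shared peak stood outside the ATHB-15 flanks, 2881 bp off in replicate 1, at 10.2-fold and 9.89-fold. PHV (AT1G30490), like REV, had no shared peak in its flanks. The nearest to PHV stood 3063 bp off in replicate 1, at 6.74-fold (5.46 to 8.23) in replicate 1 and 5.67-fold (4.47 to 7.10) in replicate 2. The share of 60% bound (exact binomial interval 14.7% to 94.7%) did not differ detectably from the 47.7% of other genes (Fisher's exact test, two-sided, adjusted p = 0.877).

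Of the 13 gene lists fixed before the data were examined, the copper deficiency list was the only one to pass. Its genes, which plants switch on or repress when copper is scarce, had a shared peak in their flanks in 17 of 19 cases, or 89.5% (66.9% to 98.7%), against 48.3% of the other genes of the same kinds (odds ratio 9.11, Fisher's exact test, two-sided, adjusted p = 0.00365 over 13 lists). The peaks were also strong: the median of each bound member's strongest peak was 14.1-fold against 4.21-fold for bound background genes, above all 10000 random lists of bound genes of that size (percentile 100). FSD1 (AT4G25100), the iron superoxide dismutase used in place of the copper enzyme, had a peak of 22.5-fold and 22.7-fold inside the gene near an annotated end, on chromosome 4 at 12886589 to 12887068. The microRNA gene MIR398B, whose product represses copper superoxide dismutases, had 21.8-fold and 22.6-fold. FRO5, of a family of metal reductases, had 21.5-fold and 22.8-fold. That summit lay 1472 bp past the higher-coordinate end of FRO5 and within 1000 bp of another coding gene. The metal transporter gene ZIP2 had 20.96-fold and 20.8-fold.

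The copper call rested on the use of shared peaks and of flanks. With the peaks of a single replicate, 17 of 19 members were again bound, but so were more of the other genes of the same kinds. Without replicate 1 the share of those other genes was 57.5% and the exact adjusted p was 0.0560. Without replicate 2 it was 57.8% and the exact adjusted p was 0.0578. With gene bodies added to the flanks the list stayed at 17 of 19 against 59.7% of the other genes of the same kinds (odds ratio 5.73, exact adjusted p = 0.109). With stronger peaks the contrast grew: among the 5000 peaks of highest fold, 73.7% of the list against 15.7% of the other genes of the same kinds had one (exact adjusted p = 3.917e-07).

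**Figure D1:**
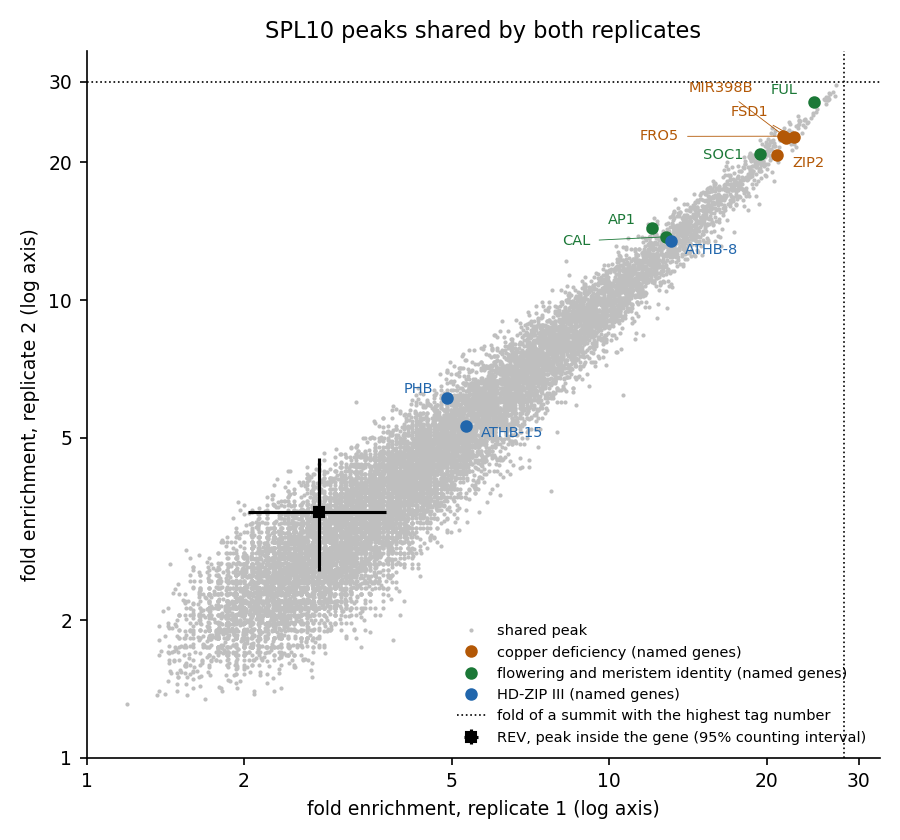
Fold enrichment of each of the 16697 shared SPL10 peaks in replicate 1 (x axis) and replicate 2 (y axis), both on log axes, with the strongest peaks of named copper deficiency, flowering and HD-ZIP III genes in colour. The peak inside REV (square, with 95% counting intervals) lies at 2.79 and 3.44, while FUL lies at 24.6 and 27.1, close to the dotted lines at 28.1 and 29.96 that mark a summit with the highest tag number found.

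Genes of flowering and meristem identity carried some of the strongest peaks of the genome, although the list did not pass the test of bound against not bound. In it, 12 of 16 genes were bound, or 75% (47.6% to 92.7%) against 47.7% of other genes (Fisher's exact test, adjusted p = 0.183). The median of their strongest peaks was 8.48-fold, at percentile 99.6 of random lists of bound genes. That percentile was not adjusted over the lists, and the random lists were not matched on gene-free bases. FUL (AT5G60910), a MADS-box gene of the floral transition, had a peak of 24.6-fold and 27.1-fold on chromosome 5 at 24506164 to 24506709, 197 bp past the gene's higher-coordinate end. The floral integrator SOC1 (AT2G45660) had 19.4-fold and 20.8-fold. The floral meristem genes AP1 and CAL had 12.1-fold and 14.3-fold, and 12.8-fold and 13.7-fold. The list passed with the 5000 peaks of highest fold (exact adjusted p = 0.0471) and with flanks of 1000 bp (exact adjusted p = 0.0449).

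The genes of the miR156 and miR172 pathways, which time the change from juvenile to adult leaves, were bound in most cases without passing the test. Among MIR156 and MIR157 genes 9 of 12 were bound (exact adjusted p = 0.211), led by MIR156D at 14.2-fold and 13.5-fold and MIR156B at 10.1-fold and 9.82-fold. The MIR156D and MIR156B summits both lay inside a protein-coding gene, the latter 1319 bp off. With flanks of 1000 bp the list of MIR156 and MIR157 genes passed (exact adjusted p = 0.0449). Of the MIR172 genes and their AP2-like targets 9 of 11 were bound (exact adjusted p = 0.183), among them the floral repressor SMZ at 12.3-fold and 12.2-fold, SNZ at 9.15-fold and 10.6-fold, TOE3 at 8.79-fold and 10.3-fold, and MIR172C at 7.45-fold and 7.18-fold. The TOE3 summit lay 1663 bp off, inside another coding gene. In the SPL family itself, 10 of 17 genes were bound (exact adjusted p = 0.869). SPL11, the neighbour and close relative of SPL10, had a peak of 23.5-fold and 24.1-fold, and SPL16 (AT1G76580) one of 16.5-fold and 17.8-fold.

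The leaf shape, hormone and comparison lists did not pass either. Of the gibberellin genes 9 of 12 were bound (exact adjusted p = 0.211), with GA20OX1, a biosynthetic oxidase, at 12.6-fold and 11.9-fold and RGA, a DELLA repressor, at 11.8-fold in each replicate. Of other leaf polarity genes 8 of 19 were bound (exact adjusted p = 0.877), with AGO1 at 7.16-fold and 7.25-fold, ZPR1 at 6.36-fold and 6.84-fold and AS2 at 4.60-fold and 4.59-fold. Among MIR165 and MIR166 genes, whose products cut HD-ZIP III transcripts, 5 of 9 were bound (exact adjusted p = 0.879), and MIR166C and MIR166D shared 1 peak of 8.93-fold and 8.84-fold. In the list of CIN-type TCP, MIR319, CUC and MIR164 genes 8 of 16 were bound (exact adjusted p = 1), with TCP5 at 13.8-fold and 14.9-fold. Trichome genes were bound in 7 of 12 cases (exact adjusted p = 0.877), with TCL1 at 9.71-fold and 10.5-fold, and flavonoid genes in 5 of 14 (exact adjusted p = 0.869), with the regulator TT8 at 9.15-fold and 10.6-fold. The comparison list of light-harvesting genes had 10 of 20 bound (exact adjusted p = 1), and the median of their strongest peaks, 7.04-fold, stood at percentile 96.5 of random lists, so a high percentile of fold was also reached by a list with no stated link to SPL10.

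**Figure D2:**
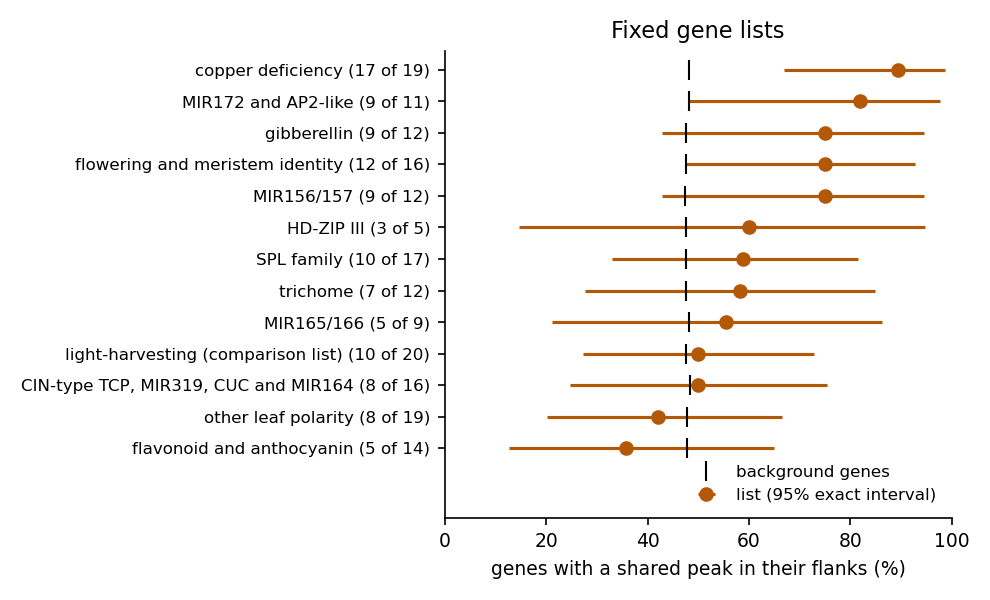
Share of each fixed gene list with a shared SPL10 peak in its flanks (points, with 95% exact binomial intervals) against the share of its background genes (ticks), in percent. The copper deficiency list, at 89.5%, is the only one whose adjusted p passed 0.05.

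Of the 10 shared peaks with the highest mean fold, 7 were named by a pseudogene, a count that was not tested against a background. They were led by a peak near AT5G34810 on chromosome 5 at 12972512 to 12974822 with 27.1-fold and 29.5-fold, outside genes and far from coding genes. The others of this kind were named by AT1G43220, AT5G29380, AT4G02317, AT1G35760, AT1G43205 and AT3G42690, of which the peak at AT1G35760 stood 3904 bp off and outside the flanks. The summits named by AT5G29380 and AT4G02317 lay 1794 and 1351 bp off, each inside another annotated gene that is not protein-coding. Over the strongest 500 peaks, 38.6% lay inside protein-coding genes. The remaining 3 were named by the coding genes AT3G10290, GIP1 (AT3G13222) and AT1G58037, the weakest of them at 26.1-fold and 27.4-fold. The summit named by AT3G10290 lay 1112 bp off, inside another coding gene. All 10 summits held between 362 and 390 of at most 396 tags in either replicate, so their order is compressed.

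How far the replicates found the same sites was tested by placing the replicate 2 peaks at random. Of the nuclear peaks, 16697 were shared by reciprocal overlap of at least 50%, which is 77.7% of replicate 1 and 78.2% of replicate 2, against 907 ± 28.7 (SD over 1000 random placements) by chance (permutation test, one-sided, p = 0.000999, the smallest that 1000 placements can give). Sharing depended on strength: 28.8% of the replicate 1 peaks in the lowest decile by fold were shared, 88.6% in the fifth decile and 98.6% in the highest. Across shared peaks, which are not independent replicates, the log2 folds correlated with Pearson's r of 0.962 and Spearman's rho of 0.942, and summits lay a median of 13 bp apart. Given the split of all tags at shared peaks (51.4% in replicate 1), the tag numbers differed with an adjusted p under 0.05 at 1 of 16697 shared peaks (exact binomial test, Benjamini-Hochberg). The variance of the tag split was 0.649 times the binomial value. Both values leave out peaks called in only 1 replicate, where larger differences could lie, so they can understate how far the replicates differed. They also compare tags at each replicate's own summit and not in a common window, so independent libraries need not reach the binomial value.

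Relative to random placement, SPL10 summits were shifted from gene bodies to the DNA between genes, by a small margin. Placement made no allowance for DNA where reads cannot be placed, so the shift need not reflect binding alone. With placement within 100 kb of each summit, the flanks outside genes held 25.9% at random against 29.8% observed. Of the shared summits, 50.9% lay inside a protein-coding gene against 54.1% ± 0.38 (SD) of randomly placed ones (0.941 times). Outside genes, 22.1% lay within 1000 bp of a coding gene against 19.04% ± 0.30 (1.16 times), and 7.71% lay 1000 to 2000 bp away against 6.25% ± 0.19 (1.23 times). Farther off, 9.70% were found against 10.6% ± 0.23 (0.914 times), although 15.2% of the strongest 500 shared peaks lay there, a share not tested. All 4 differences from random placement had an adjusted p of 0.0025 (permutation test, two-sided, 1000 placements, Benjamini-Hochberg over 5 classes), while summits inside other annotated genes, at 9.59% against 10.0%, did not pass (adjusted p = 0.0759). The share in the flanks outside genes was 29.8% over all shared peaks and 34.3% over those among the 5000 of highest fold. When a flank was counted before a gene body, a setting chosen after seeing the data, the share was 65.01% against 63.4% at random, a smaller excess than the 29.8% against 25.3% of the main setting.

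**Figure D3:**
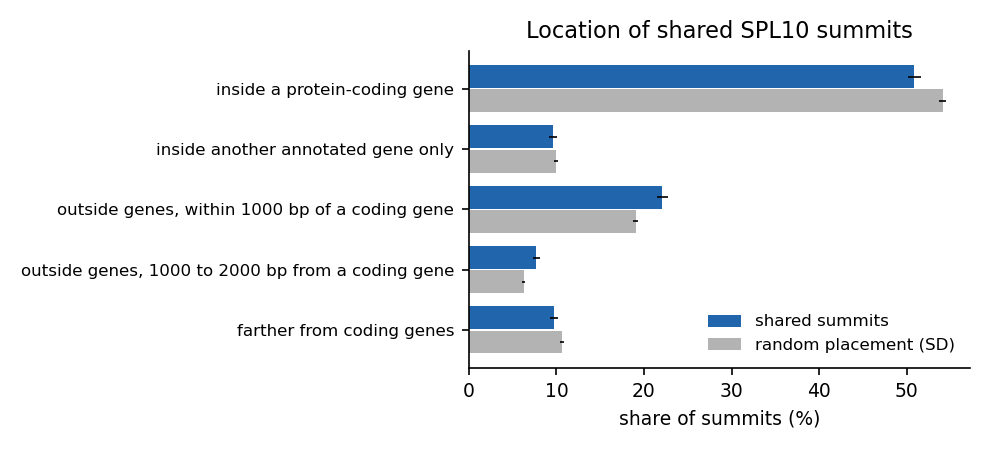
Share of shared SPL10 summits in each kind of location (blue, with 95% Wilson score intervals) and of randomly placed summits (grey, with the SD over 1000 placements), in percent of summits. Coding genes hold 50.9% against 54.1% at random, and the 1000 bp around them 22.1% against 19.04%.

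With flanks of 2000 bp, 18073 of 37899 nuclear genes (47.7%) had a shared peak, including 13251 of 27444 protein-coding genes and 158 of 326 microRNA genes. Random placement of the same number of summits reached 45.9% ± 0.27 (SD, permutation test, two-sided, p = 0.002, the smallest that 1000 placements can give), so a peak in the flanks of a single gene says little. The count depended on the setting and was 10402 with −log10 q of at least 10, 5955 with the 5000 peaks of highest fold and 11346 with flanks of 1000 bp.

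Peaks covered the chromosomes evenly, with 137 to 142 shared summits per Mb on each of the 5. The 298 gene-poorest of the 1193 bins of 100 kb held fewer summits than random placement gave (0.895 times, permutation test, two-sided, adjusted p = 0.00799), and the 3 richer sets of bins held 1.04, 1.04 and 1.03 times as many, in order of rising gene number (adjusted p = 0.00799, 0.0133 and 0.0460). Placement kept the number of summits per chromosome, so a deficit in some bins has to appear as an excess in others. The excesses in the richer bins are therefore not results separate from the deficit. Nor did placement allow for DNA where reads cannot be placed, so the deficit in gene-poor bins is not by itself evidence of a binding preference. Across all bins, which are not independent, summit number and gene number correlated with a Spearman's rho of 0.156, and of 0.0628 with the 5000 peaks of highest fold.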

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

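All tests in this part were chosen only after the result was seen, except the density of the strongest 500 peaks and the 2 tests of the copper list, which were written down before their outcome.

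Signal appeared in data outside the main measurement: replicate 1 listed 74 mitochondrial peaks and replicate 2 listed 76. Their median folds were 1.804 and 1.86, with 311.5 and 308 tags and a background 12.9 and 12.99 times the genome level. On chromosome 2, between 3241467 and 3505279, 51 and 56 nuclear peaks had a similarly raised background of 11.97 and 11.8 times the genome level.

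The fold of the strongest peaks stopped at a ceiling, and the replicates differed by less than binomial sampling gives at their shared peaks. Tags were compared at each replicate's own summit, so independent libraries need not reach the binomial value. The highest summit in either list held 396 tags, as keeping 1 tag per position and strand in a window of 198 bp would give, and a limit set by SPL10 binding is argued against because the highest mitochondrial summit reached 100% of the highest nuclear one at a far lower fold. The ceiling may account for part of the evenness of the replicates, since the variance ratio was 0.743 at 40 to 60 mean tags and 0.338 above 200. Simulated independent libraries with that ceiling missed in both directions, with 0.815 to 0.884 at 40 to 60 tags, 0.595 to 0.656 against 0.587 observed at 100 to 200 and 0.146 to 0.208 above 200, and matched at 60 to 100 tags (0.7495 observed, 0.721 to 0.790 simulated). The simulated strengths were not matched to the data: 3376 of 8000 simulated peaks but 732 of 16697 shared peaks fell in the group above 200. With an assumed tag profile and assumed strengths, the simulation leaves the question open. Reads shared by the libraries were not tested, and for the evenness no biological explanation was tested.

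The high share of copper deficiency genes bound, 89.5%, was set against technical explanations that concern flank width and neighbouring genes only. The series had no mock precipitation, so recovery of these sites independent of SPL10 could not be tested. Wider gene-free flanks are argued against because random lists matched on gene-free bases gave 26.3% to 73.7%. Neighbouring genes counted together through a common peak are argued against because no members shared a peak, so the list formed 19 groups. The share of groups bound, 89.5% against 26.3% to 68.4% in random lists, therefore repeats the main result and adds no evidence. This grouping does not address neighbours that each had a separate peak, such as FRO4 and FRO5 or MIR398B and MIR398C. A candidate explanation is that SPL10 binds the GTAC sites through which SPL7, another SBP protein, acts on these genes. This stays an untested hypothesis, since no sequence was used.

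Among the very strongest peaks, gene-poor DNA was over-represented at some sizes of the top set and not at others. The 298 gene-poorest of 1193 bins held 22.4% of all shared peaks, but 6 of the 10 strongest (adjusted p = 0.0225 over 4 sizes, exact binomial test), 22 of the 50 strongest (adjusted p = 0.00368), 30 of the 100 strongest (adjusted p = 0.0957) and 122 of the 500 strongest (adjusted p = 0.283). Per Mb, the strongest 500 were 0.969 times as dense there as elsewhere (0.784 to 1.19), which fewer weak peaks without an excess of strong ones would give, while the figure for the 50, 2.36 times (1.29 to 4.28), restates the observation and tests nothing further. Extra copies that raise the background library too stay open: the median background was 1 times the genome level for the 50 and for the 500, but the peaks were ranked by fold, which divides by that background, so this value was set by the ranking.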

How the results depend on the processing

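Of 212 values under alternative settings, 177 met the rule for no change: tested values kept their direction and their side of the threshold whatever their size, counts lay within 1.5 times and correlations within the 95% interval (Fisher's z) of the main one. Some could not change, since lists holding microRNA genes already had a background of the same gene kinds. Most of the 212 belong to lists that did not pass in the main setting, so the count does not measure robustness. The rank correlation of fold between replicates was 0.936 with any overlap, 0.946 with summits within 50 bp, 0.945 with −log10 q of at least 10 and 0.938 with q of at most 0.05, and that of summit and gene number was 0.0628 with the 5000 peaks of highest fold. Peaks per replicate fell to 9582 and 9607 with −log10 q of at least 10. Bound genes numbered 10402 with that limit, 5955 with the 5000 peaks of highest fold and 11346 with flanks of 1000 bp. The number of lists that passed was 2 with the 5000 peaks and 3 with flanks of 1000 bp, but 0 with gene bodies added, and 0 with either replicate alone. The copper share stayed at 89.5% with gene bodies (exact adjusted p = 0.109) and with either replicate alone, where unshared peaks raised the background. Its adjusted p ranged from 3.917e-07 to 0.109 over all settings. REV had 0 shared peaks with −log10 q of at least 10 and 0 among the 5000 peaks, against 3 with a single replicate. The cause was not tested.

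Some lists that passed no test in any setting moved to the other side of their background. Other leaf polarity stood at 42.1% with flanks of 1000 bp and 78.9% with gene bodies, MIR165 and MIR166 at 22.2% both with −log10 q of at least 10 and with flanks of 1000 bp, trichome at 8.33% with the 5000 peaks, flavonoid at 50% with any overlap and with summits within 50 bp and at 57.1% to 64.3% with a single replicate, TCP, CUC and their microRNA genes at 56.2% with gene bodies and 56.2% without replicate 1 (but 68.8%, on the same side as before, without replicate 2), and light-harvesting at 45.0% with summits within 50 bp. The cause was not tested. The GTAC search and the background matched on GTAC were not run. No paired analysis was possible because a single group had replicates. Recovered tag numbers limit precision: the peaks at REV, with 30 to 48 tags, have wide counting intervals.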

Other observations

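The screen of genes grouped by symbol was chosen after the data were seen. Grouping used the symbol only, so a group need not be a family by descent. Among 172 groups with at least 10 coding members of a common symbol, 0 passed Fisher's exact test after Benjamini-Hochberg adjustment, and 9 had an unadjusted p under 0.05. The group with the lowest p was MPK, the mitogen-activated protein kinases, with 15 of 18 genes bound against 48.3% of coding genes (exact p = 0.00349, adjusted p = 0.600). PRA genes had 3 of 18 bound (exact p = 0.00813, adjusted p = 0.699).

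By kind of gene, 45.0% of pseudogenes had a shared peak in their flanks, against 48.3% of protein-coding genes and 35.7% of tRNA genes. Among copper deficiency genes, the bound members outside the strongest 4 included MIR398C at 19.8-fold and 19.6-fold, MIR408 at a mean of 18.6-fold and MIR857 at a mean of 17.5-fold, named here after their values were seen. CSD2 and MIR398A were the 2 members without a shared peak in their flanks.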
